A study of Bos taurus with 12 samples.

How the data were processed

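Per the submitters' protocol notes, biotin-labelled cRNA was prepared from total RNA and hybridized to the Affymetrix bovine array. The submitters' processing notes name GCOS 1.1.1 and Affymetrix Expression Console 1.1. The summarization algorithm and the normalization behind the deposited intensity values are not given in the sources used here. The deposited values were linear intensities of 24128 probe sets in 12 samples, with 2303 zeros and a maximum of 222742. They were used as deposited apart from the steps below, and no per-sample column was left out.

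The signals were turned into log2(signal + 16), and the arrays were quantile normalized. The design set before the data were examined provided for this normalization when the quantiles of an array lay apart, which those of HS IMF 3 did. The 112 control probe sets were left out, and of the other 24016 the 30% with the lowest mean were left out as dim, which left 16811. Of the 24016, 13292 carried 1 gene symbol, 86 several and 10638 none. Symbols were updated through the Entrez gene identifier, which matched for 13283 of 13318 annotated probe sets with 1 symbol. Neighbours of a gene were taken from the RefSeq annotation of assembly ARS-UCD2.0.

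Linear models with 4 group means over the 12 samples were fitted with limma 3.58.1 (lmFit, eBayes; 8 residual and 4.05 prior degrees of freedom) in R 4.3.3. Breed was compared within IMF and within SCF, depot over both breeds and within each, and the interaction was the breed difference in IMF minus that in SCF. Probe sets passed at a Benjamini-Hochberg adjusted p below 0.05 within a comparison. The 26 gene lists with at least 4 measured genes were tested with camera at its preset correlation of 0.01 and adjusted by Benjamini-Hochberg over the lists of a comparison. Each gene entered the list tests once, through its brightest probe set, and members of lists are given through that probe set. Genes named for the largest change are given through the probe set with the largest change, and genes named for the smallest p through the probe set with the smallest p. Files were read with jsonlite 2.0.0, and figures were drawn with Python 3.11.15, matplotlib 3.10.9 and numpy 2.4.6.

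The comparisons, lists, threshold, filters, rule for naming genes and first set of other settings were fixed before the data were examined. Genes were named by this rule: the 8 largest increases and 8 largest decreases past the threshold whose sides did not overlap and that carried 1 symbol, or the 5 smallest p where fewer than 3 passed in a direction; up to 4 members with the smallest p of each list that passed or had a member past the threshold; the 5 smallest p in each direction for the interaction; and ASIP in every comparison, because earlier work on these breeds pointed to it. Between 3 and 3 samples, complete separation arises by chance for 10% of genes. These settings were no filter, 50% left out as dim, median centring, a pseudocount of 1, a trended and robust variance model, array weights, only the compared groups in the fit, 1 probe set per gene, treat against 1.2-fold, a replicate block, each sample left out, other probe sets of a gene, an estimated correlation and fry. Chosen after the data were seen were the values as deposited, removal of HS IMF 3 and HS SCF 4, removal of JB SCF 6 and HS SCF 5, and a muscle marker covariate.

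The procedure was tried on simulated data of 16811 probe sets, 200 of them changed in each comparison. For changes of 2-fold, 4-fold and 8-fold it recovered 10.4%, 82.1% and 97.0% in IMF between breeds, 14.9%, 79.1% and 98.5% in SCF, 55.2%, 95.5% and 97.0% between depots, and 1.49%, 49.3% and 93.9% for the interaction. False calls were 3, 9, 8 and 9 of 16611 unchanged probe sets. The 1 list shifted by 1 log2 unit was called in each of the 4 comparisons, and 0 of the other lists were. The simulated genes varied independently and with the same spread in every group. The simulation therefore says nothing on false calls of lists whose genes vary together. In regrouped real samples, described below, the median number of lists called was 5 for breed in IMF, 6 for breed in SCF, 5 for depot and 5 for the interaction.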

Results

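Gene expression was measured in the fat of Japanese Black (JB) and Holstein (HS) steers kept on an energy-rich diet. JB is a beef breed known for heavily marbled meat, and HS is a dairy breed. Intramuscular fat (IMF), which lies between the fibres and bundles of a muscle, and subcutaneous fat (SCF), which lies under the skin, were sampled in both breeds. The 4 groups of breed and depot held 3 samples each, 12 in all, numbered 1 to 3 in IMF and 4 to 6 in SCF within each breed. Labelled RNA of each sample was hybridized to the Affymetrix bovine array, and 16811 probe sets standing for 7808 named genes and further unnamed transcripts were tested. The number of arrays, 3 per group, limits the precision. The labels state neither that the samples of a group came from separate animals nor whether IMF and SCF samples share animals, so the p-values measure the spread between these samples, which may be partly technical.

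The median signal of the deposited arrays lay between 77.6 and 88.3, except in HS IMF 3 at 58.8. HS IMF 3 also had the lowest mean correlation with its own group, 0.805, and in SCF the lowest was that of HS SCF 4, 0.875. Every HS sample lay below every JB sample in this measure, at 0.805 to 0.915 against 0.944 to 0.962. The spread within groups thus differed with breed, while the model shares its spread estimate over all groups. The 3'/5' signal ratio of the GAPDH control, which rises as RNA degrades, was 4.06 in HS SCF 5 and 1.19 to 2.40 in the others, and that of cyclophilin was 3.35 in HS IMF 1 and 1.88 to 2.85 in the others. Quantile normalization was therefore applied, by a rule set beforehand. All log2 differences are on the scale of log2(signal + 16), which understates the change of dim genes. The median difference over all probe sets between the breeds in IMF was 0.10 after quantile normalization and 0.37 in the values as deposited, so that differences in IMF are relative to this shift.

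The breeds were first compared within IMF, as the series' design text names it. ASIP, which encodes agouti signalling protein, an antagonist of melanocortin receptors known from coat colour, was higher in JB by 3.40 ± 0.40 (SE) on the log2 scale, 10.5-fold. Its deposited signal was 355 to 678 in the 3 JB samples and 19.9 to 25.7 in the 3 HS samples. PDE4DIP, which encodes myomegalin, a protein of the Golgi apparatus and centrosome, was higher in JB by 2.79 ± 0.29 (SE), 6.91-fold, with signals of 356 to 817 against 45.1 to 45.4. LTBP2, an extracellular matrix protein of the latent TGF-beta binding family, was higher in JB by 2.25 ± 0.30 (SE), 4.77-fold, with signals of 288 to 457 against 25.2 to 77.9. In SCF the LTBP2 signals were also higher in JB, 176 to 253 against 59.2 to 80.5, though it did not pass there. NNAT, the imprinted gene of the membrane proteolipid neuronatin, differed by −3.00 ± 0.39 (SE), with signals of 44.5 to 111 in JB and 322 to 943 in HS.

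These 4 probe sets, 3 higher and 1 lower in JB, were the ones past the threshold in IMF by limma with Benjamini-Hochberg adjustment, at adjusted p = 0.0151 for ASIP, 0.00801 for PDE4DIP, 0.0279 for LTBP2 and 0.0277 for NNAT. The 3 JB samples did not overlap the 3 HS samples for any of them. At an unadjusted p under 0.05 there were 1720 probe sets, where 840.55 would be reached with no difference. The next genes lower in JB did not pass by limma with Benjamini-Hochberg adjustment. They were DLX5, a homeobox transcription factor (log2 difference −1.43, adjusted p = 0.399), SESN2, a stress-inducible regulator of mTORC1 (−0.97, adjusted p = 0.418), THBS1, the matrix glycoprotein thrombospondin 1 (−1.31, adjusted p = 0.418) and GHRH, growth hormone-releasing hormone (−1.22, adjusted p = 0.485). Of 5 other tested probe sets of THBS1, 4 were positive, the brightest at 0.28 and the others at 0.71, 0.33 and 0.24, and another tested probe set of SESN2 was at 0.36, so that the sign of these 2 genes depends on the probe set.

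ASIP is read by 1 probe set, and no other probe set of the remaining genes passed by limma with Benjamini-Hochberg adjustment. The other LTBP2 probe set differed by 1.18 (adjusted p = 0.485) and the other NNAT probe set, too dim to be tested with the others, by −0.95 (adjusted p = 0.519). Of the other PDE4DIP probe sets, 3 differed by 0.62, 0.71 and 1.60 and the brightest of all by −0.84 (adjusted p = 0.485), the opposite direction. With only the IMF samples in the fit, or with array weights, none of the 4 passed. With a pseudocount of 1, ASIP (adjusted p = 0.474) and LTBP2 (0.0752) did not pass. In the values as deposited NNAT, the one gene lower in JB, was lost (−2.67, adjusted p = 0.118) and NDUFS3 passed, giving 4 higher and 0 lower. Over 26 alternatives PDE4DIP passed in 22 (adjusted p from 0.00456 to 0.545), ASIP in 17 (0.00734 to 0.474), NNAT in 13 (0.00982 to 0.292) and LTBP2 in 7 (0.0178 to 0.763).

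With 1 sample left out at a time, PDE4DIP passed in 11 of 12 fits (limma, Benjamini-Hochberg adjusted p from 0.00963 to 0.0812), ASIP in 8 (0.0114 to 0.0837), NNAT in 4 (0.00982 to 0.238) and LTBP2 in 2 (0.0185 to 0.263). PDE4DIP was lost without HS IMF 1 (adjusted p = 0.0812). ASIP was lost without JB IMF 2 (0.0700), JB IMF 3 (0.0574), HS IMF 1 (0.0837) and HS IMF 3 (0.0781). NNAT passed only without JB IMF 1, HS IMF 2, HS SCF 4 or HS SCF 5, and LTBP2 only without HS IMF 2 or HS SCF 4. The count of probe sets past the threshold was 0 without HS IMF 1, 1 without JB IMF 3, 2 without each of JB IMF 2, JB SCF 4, JB SCF 5, JB SCF 6, HS IMF 3 and HS SCF 6, 3 without JB IMF 1 or HS SCF 5, 6 without HS SCF 4 and 7 without HS IMF 2.

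**Figure D1:**
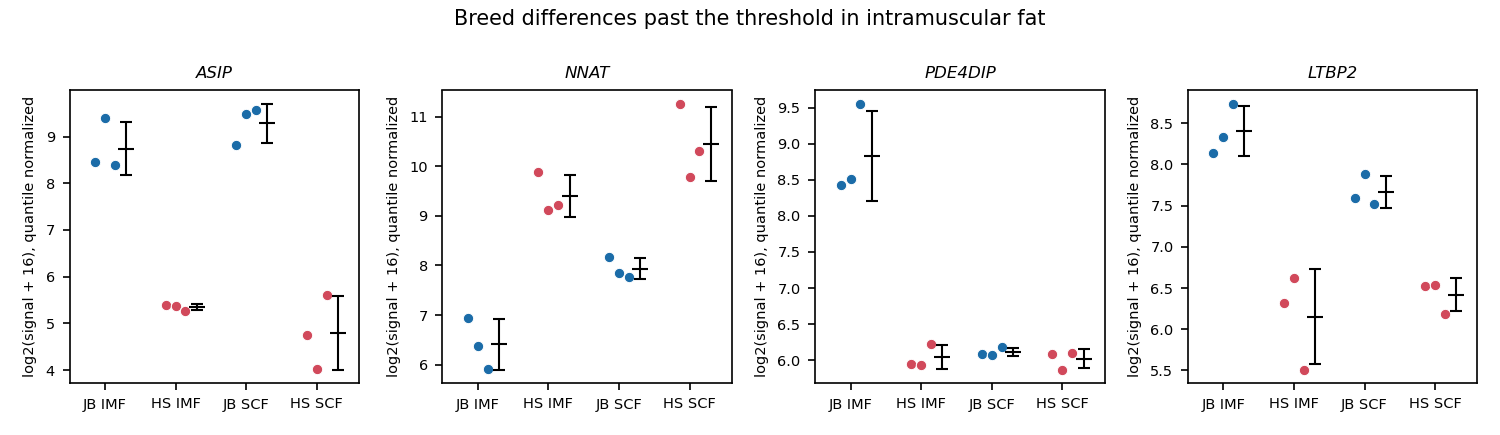
Normalized log2(signal + 16) of the named breed genes in each of the 12 samples, by group of breed and depot; points are samples and bars are the mean ± SD of 3 samples. ASIP stood at 8.74 and 9.29 on average in JB IMF and JB SCF, against 5.35 and 4.80 in HS IMF and HS SCF.

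Among 26 gene lists fixed before the data were examined, the smooth muscle and pericyte list was higher and the erythroid list lower in JB IMF. All 9 measured smooth muscle and pericyte genes had positive differences, with a median of 0.88. Examples are RGS5, a pericyte regulator of G-protein signalling (2.43 ± 0.85 SE), SMTN, the cytoskeletal protein smoothelin (1.46 ± 0.41), MYH11, smooth muscle myosin (1.22 ± 0.56) and ACTA2, smooth muscle actin (0.88 ± 0.41). None of the 9 passed over all genes and 1 passed when adjusted over the list alone. The list passed with camera of limma (Benjamini-Hochberg adjusted p = 0.00233), and its adjusted p = 0.693 with an estimated correlation. All 6 erythroid genes had negative differences, with a median of −1.04, among them HBB, a beta globin (−1.53 ± 0.66), HBM, a globin of the alpha cluster (−1.27 ± 0.51), HBA, alpha globin (−0.80 ± 0.42) and ALAS2, the first enzyme of erythroid heme synthesis (−0.69 ± 0.33). None of the 6 passed, over all genes or adjusted over the list alone. The list had a camera Benjamini-Hochberg adjusted p = 0.00233 and an adjusted p = 0.693 with an estimated correlation. The erythroid mean was 8.80 in HS IMF 3 and 6.05 to 7.25 in the other samples. Without HS IMF 3 the median of the list was −0.40 and the camera adjusted p was 0.0513.

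Of the 6 measured genes of the agouti and melanocortin list, ASIP alone passed in IMF, over all genes and adjusted over the list alone. The melanocortin receptor genes MC2R (−0.60 ± 0.35), MC1R (−0.48 ± 0.24) and MC4R (−0.38, with an SE larger than the difference) did not. The list as a whole did not pass (limma camera, Benjamini-Hochberg adjusted p = 0.996); its median, −0.17, and mean, 0.33, differed in sign. The lowest adjusted p among the lists that did not pass in IMF was 0.0924 by camera with Benjamini-Hochberg adjustment, shared by the cholesterol synthesis and uptake, endothelial cell and thermogenic adipocyte lists, whose medians were 0.57, −0.27 and −0.47.

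The breeds were next compared within SCF. ASIP was higher in JB by 4.49 ± 0.40 (SE) on the log2 scale, 22.5-fold, with signals of 493 to 788 in the 3 JB samples and 0.06 to 33.9 in the 3 HS samples. The HS signals lie near the background, so the fold depends on the 16 added to each signal (log2 difference 6.25 with 1 added). It was the only probe set past the threshold in SCF by limma with Benjamini-Hochberg adjustment (adjusted p = 0.00147), and 599 passed at an unadjusted p under 0.05, fewer than the 840.55 reached with no difference. It passed in 23 of 26 alternatives (limma, Benjamini-Hochberg adjusted p from 0.000270 to 0.239), and not with a pseudocount of 1 (0.239), with only the SCF samples in the fit (0.0965), or without both JB SCF 6 and HS SCF 5 (0.0584). The count was 2 without JB IMF 1, where IL6 also passed, and 2 without HS SCF 4, where SELE, the endothelial adhesion molecule E-selectin, also passed. SELE is named after its values were seen.

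Several other genes separated the 3 JB from the 3 HS subcutaneous samples without passing the threshold by limma with Benjamini-Hochberg adjustment. Positive differences were those of IL6, the cytokine interleukin 6 (2.79 ± 0.41 SE, signals 915 to 1217 against 94.0 to 157, adjusted p = 0.155), GRO1, a neutrophil-attracting chemokine (1.54 ± 0.26, adjusted p = 0.243), SPRY1, an inhibitor of receptor tyrosine kinase signalling (1.29 ± 0.23, adjusted p = 0.262) and BOLA-N, an MHC class I gene (2.77 ± 0.50, adjusted p = 0.262). In IMF the BOLA-N signals were also higher in JB, 1034 to 2101 against 127 to 394, without passing. Negative differences were those of NNAT (−2.52 ± 0.39, adjusted p = 0.155), MME, the membrane peptidase neprilysin (−2.38 ± 0.45, adjusted p = 0.329), CYP1A1, a cytochrome P450 induced through the aryl hydrocarbon receptor (−2.48 ± 0.49, adjusted p = 0.368), NR0B1, an orphan nuclear receptor (−1.20 ± 0.27, adjusted p = 0.627), and NR1D1, the circadian nuclear receptor REV-ERB alpha (−1.47 ± 0.35, adjusted p = 0.749). Other probe sets of GRO1 differed by 1.64, 0.85 and, for the brightest, −0.17. Another tested probe set of NR0B1 was at −0.046. Further probe sets of CYP1A1 (−0.15 and −0.22), MME (−1.29) and NNAT (−1.90) were too dim to be tested with the others.

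In SCF, 2 lists were higher and 3 lower in JB by camera, and each of these calls was lost with an estimated correlation. The immediate early and stress list was higher, with 14 of 19 genes positive and a median of 0.49 (limma camera, Benjamini-Hochberg adjusted p = 1.66e-05; adjusted p = 0.809 with an estimated correlation). None of its genes passed over all genes and 5 passed when adjusted over the list alone; examples are ATF3, a stress-induced transcription factor (1.51 ± 0.38 SE), NR4A1, an immediate early nuclear receptor (1.46 ± 0.34), ZFP36, a regulator of mRNA decay (1.42 ± 0.31) and IER2, an immediate early gene (1.07 ± 0.27). Without HS SCF 6, the sample with the lowest mean of this list (10.4, against 10.8 to 11.5 in the other samples), the camera adjusted p was 0.186. The macrophage and myeloid cell list was higher, with 12 of 14 genes positive and a median of 0.47 (camera, Benjamini-Hochberg adjusted p = 0.00493; adjusted p = 0.809 with an estimated correlation). Its examples are the complement genes C1QA (1.11 ± 0.47) and C1QC (1.03 ± 0.47) and the monocyte chemokine CCL2 (1.73 ± 0.75). None passed, over all genes or adjusted over the list alone. Without JB SCF 5 and without JB SCF 6 the camera adjusted p was 0.0555 and 0.192.

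The 3 lists lower in JB SCF were metabolic. Of the fatty acid synthesis genes, 16 of 18 were negative, with a median of −0.28 (camera, Benjamini-Hochberg adjusted p = 0.0112; adjusted p = 0.809 with an estimated correlation), among them ACLY, ATP citrate lyase (−0.60 ± 0.36 SE) and SLC25A1, the mitochondrial citrate carrier (−0.84 ± 0.66). Of the triacylglycerol synthesis genes, 9 of 11 were negative, with a median of −0.37 (adjusted p = 0.0330 by the same test; adjusted p = 0.809 with an estimated correlation), among them PCK1, of glyceroneogenesis (−0.93 ± 0.52), and the acyl-CoA synthetase ACSL1 (−0.68 ± 0.39). Of the respiratory chain genes, 19 of 21 were negative, with a median of −0.13 (adjusted p = 0.0351 by the same test; adjusted p = 0.937 with an estimated correlation), such as COX5B, of complex IV (−0.40 ± 0.27). No gene of these 3 lists passed, over all genes or adjusted over the list alone. Without JB SCF 6 the camera adjusted p values were 0.192, 0.192 and 0.659, at medians of −0.16, −0.30 and 0.0061. Without HS SCF 6 they were 0.314, 0.590 and 0.952, at medians of −0.10, −0.067 and 0.11. Without both JB SCF 6 and HS SCF 5 they were 0.348, 0.337 and 0.601, and 0.413 for the macrophage list. In the values as deposited the respiratory chain list was lost (median −0.044, adjusted p = 0.144).

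ASIP was again the one gene of 6 in the agouti and melanocortin list to pass in SCF, over all genes and adjusted over the list alone. POMC, the precursor of melanocortin peptides, differed by 0.13 ± 0.22 (SE) and by −0.54 on another probe set, MC1R by −0.21 ± 0.24 and MC4R by −2.11, its signal being 1515 in HS SCF 4. The list did not pass with camera (Benjamini-Hochberg adjusted p = 0.739). It passed with fry of limma, which tests whether the genes move one way on balance (Benjamini-Hochberg adjusted p = 0.0328), while its median, −0.08, and mean, 0.36, differed in sign. The fibrillar collagen and matrix list, with a median of 0.19, had the lowest camera adjusted p among the lists that did not pass in SCF, 0.0774.

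IMF was then compared with SCF over both breeds, 6 samples against 6. The largest differences were those of skeletal muscle genes, all higher in IMF. MYH1, a fast myosin heavy chain, was higher 511-fold (SE 0.29 on the log2 scale), with signals of 4636 to 14552 in the 6 IMF samples and 0 to 18.8 in the 6 SCF samples. This fold too depends on the 16 added (log2 difference 11.79 with 1 added). MYL2, a slow myosin light chain, was higher by 8.30 ± 0.59, and differences of 7.42 to 7.61 were found for the myosins MYH7, MYL11 and MYL1, the Z-disc protein MYOT, the troponin TNNC1 and SLN, a regulator of the sarcoplasmic calcium pump. Other probe sets named for MYH7 and MYL11, brighter than these, differed by 0.56 and 0.70 and did not pass.

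Of the 8 genes named for the largest decreases in IMF, TF, transferrin, the iron carrier of plasma, fell by 4.47 ± 0.61 (SE) on the log2 scale, with signals of 58.5 to 523 in IMF and 986 to 9055 in SCF. TDH, L-threonine dehydrogenase of threonine breakdown, fell by 3.71 ± 0.53. VSIG4, a complement receptor of tissue macrophages, CFB, complement factor B, F13A1, the coagulation factor XIII subunit made by macrophages, FCN1, a ficolin of the lectin complement pathway, and the chemokine GRO1, here read by another probe set than between the breeds, differed by −3.31, −3.22, −3.21, −3.13 and −2.79. ENPP5, of the ectonucleotide pyrophosphatase family, fell by 2.60 ± 0.23. ASIP did not differ between the depots (0.0038 ± 0.28 SE, limma, Benjamini-Hochberg adjusted p = 0.995).

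By limma with Benjamini-Hochberg adjustment, 1848 probe sets passed between the depots, 784 higher and 1064 lower in IMF, standing for 414 and 684 named genes and 310 and 315 unnamed probe sets. Differences were over 2-fold for 591 of the higher and 495 of the lower probe sets. The adjusted p was 6.72e-09 for MYH1, 3.63e-06 for MYL2, 0.000724 for TF and 2.07e-05 for ENPP5. In the values as deposited, 586 were higher and 1319 lower, so that the share of higher calls was 42.4% after quantile normalization, 38.8% after centring each array on its median and 30.8% as deposited. The total was 799 without both JB SCF 6 and HS SCF 5, and 1000 without JB IMF 1, 942 without JB IMF 3, 1014 without JB SCF 5, 1119 without JB SCF 6 and 1063 without HS SCF 6.

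The skeletal muscle fibre list was the one that differed most between the depots. Of its 27 measured genes, 24 passed as higher in IMF and none as lower, and all 27 passed as higher when adjusted over the list alone, with a median of 6.29. Examples are the fast-fibre genes MYOZ1 (6.95 ± 0.33 SE), TNNT3 (7.10 ± 0.33), ACTN3 (6.89 ± 0.29) and ATP2A1 (5.45 ± 0.21). Of the muscle genes named above, MYOT and SLN are not in this list. MYH7 and MYL11 enter it through their brighter probe sets, which did not pass over all genes. The list passed with camera of limma (Benjamini-Hochberg adjusted p = 1.24e-41; adjusted p = 0.0453 with an estimated correlation). Its mean over genes was 11.5 to 12.7 in the IMF samples and 5.88 to 8.01 in the SCF samples, where JB SCF 6 at 7.94 and HS SCF 5 at 8.01 were the highest. IMF samples thus carried the transcripts of muscle fibres at high levels, a measured fact that stands beside each gene group compared between the depots.

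Of the 9 smooth muscle and pericyte genes, 7 passed as higher in IMF and 2 did not pass, with a median of 2.53 (camera, Benjamini-Hochberg adjusted p = 4.05e-09; adjusted p = 0.0453 with an estimated correlation). Adjusted over the list alone, 8 were higher and 1 lower. CNN1, the smooth muscle protein calponin 1, rose by 3.72 ± 0.32 (SE), MYH11 by 3.73 ± 0.40, TAGLN, transgelin, by 2.92 ± 0.32 and ACTA2 by 2.91 ± 0.29. Of the 7 satellite cell and myogenic factor genes, 3 were higher, MYF6, a myogenic transcription factor (5.05 ± 0.41), DES, the muscle intermediate filament desmin (4.86 ± 0.36), and CHRNA1, the muscle acetylcholine receptor (0.79 ± 0.23), while VCAM1, an adhesion molecule also of endothelium, was lower (−1.66 ± 0.43). Adjusted over the list alone, 5 were higher and 1 lower. CHRNA1 passed in 11 of 24 alternatives (limma, Benjamini-Hochberg adjusted p from 0.0129 to 0.189) and VCAM1 in 13 of 24 (0.00917 to 0.120). The satellite cell list had a median of 0.79 and passed with camera (Benjamini-Hochberg adjusted p = 0.000254; adjusted p = 0.116 with an estimated correlation).

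The macrophage and myeloid cell list was lower in IMF. Of its 14 genes, 11 passed as lower and none as higher, 12 passed as lower when adjusted over the list alone, and the median was −1.63. The complement genes C1QB, C1QA and C1QC differed by −2.52 ± 0.37 (SE), −2.48 ± 0.33 and −2.46 ± 0.34, and CD14, the lipopolysaccharide co-receptor, by −2.19 ± 0.27. The list passed with camera of limma (Benjamini-Hochberg adjusted p = 4.58e-08; adjusted p = 0.353 with an estimated correlation). The mean of the list was 8.59 ± 0.55 (SD, n = 6) in IMF and 10.3 ± 0.57 (SD, n = 6) in SCF, lower in IMF while the skeletal muscle fibre mean was higher in every IMF sample.

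**Figure D2:**
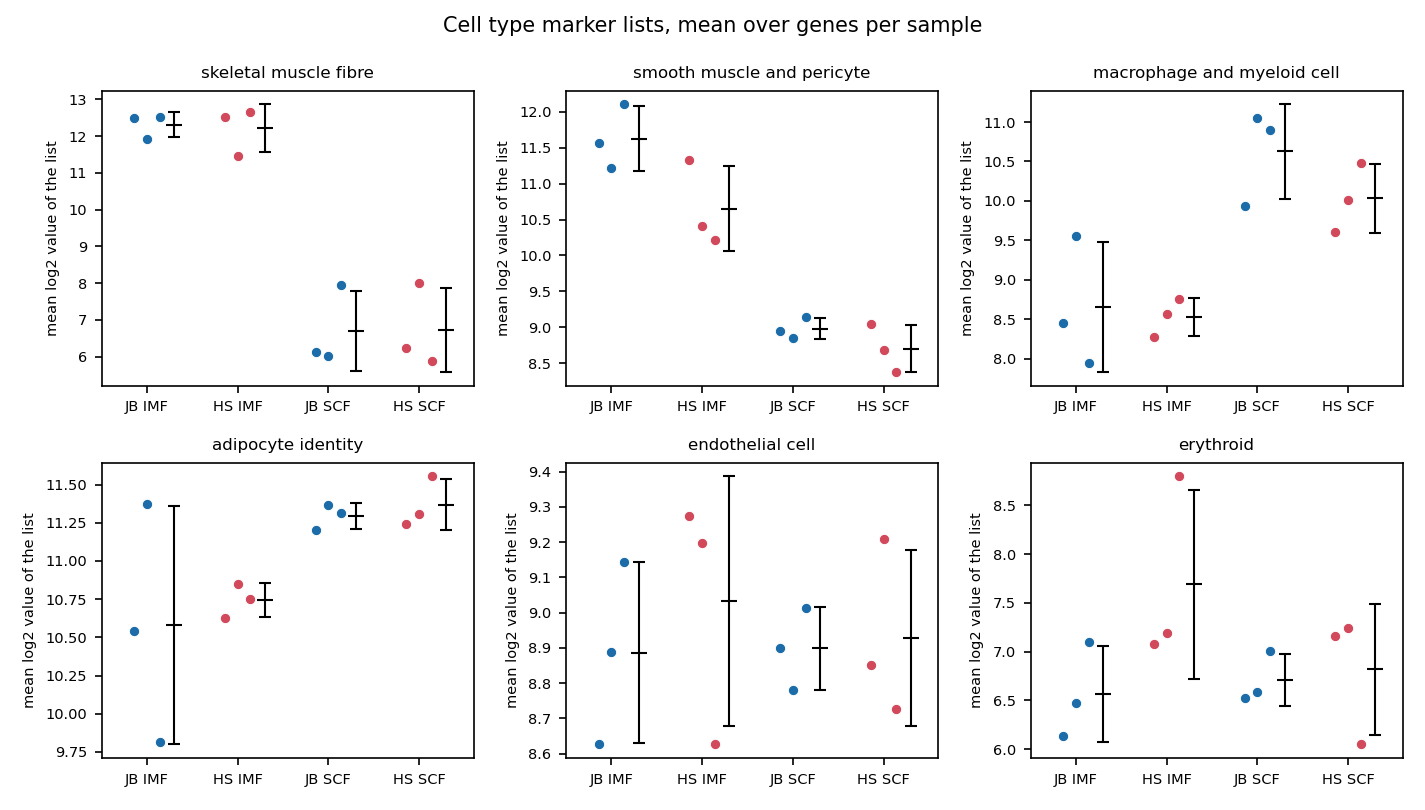
Mean of normalized log2(signal + 16) over the genes of marker lists in each of the 12 samples, by group of breed and depot; points are samples and bars are the mean ± SD of 3 samples. The skeletal muscle fibre mean was 11.5 to 12.7 in IMF and 5.88 to 8.01 in SCF.

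Of the 17 lymphocyte and antigen presentation genes, 4 were lower in IMF and 13 did not pass, and 5 were lower when adjusted over the list alone. PTPRC, the leukocyte antigen CD45, differed by −1.53 ± 0.31 (SE), JCHAIN, the joining chain of secreted antibodies, by −2.29 ± 0.54, the chemokine CCL5 by −1.28 ± 0.34 and the MHC class II chain BOLA-DRA by −1.15 ± 0.32. BOLA-DRA passed in 13 of 24 alternatives (limma, Benjamini-Hochberg adjusted p from 0.00860 to 0.150) and CCL5 in 14 of 23 (0.0131 to 0.113). The lymphocyte list did not pass with camera (median −0.74, Benjamini-Hochberg adjusted p = 0.109), nor did the interferon response list, none of whose 11 genes passed (median −0.63, adjusted p = 0.109).

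Among the lipid lists, fatty acid synthesis was lower in IMF, with 6 of 18 genes lower and 1 higher, and 13 lower and 1 higher when adjusted over the list alone. PGD and TKT, of the pentose phosphate pathway, differed by −1.61 ± 0.34 (SE) and −1.22 ± 0.22, and ACLY by −1.10 ± 0.25. ACACB, the mitochondrial acetyl-CoA carboxylase of muscle, which restrains fatty acid oxidation, was higher by 3.63 ± 0.31. The list had a median of −0.97 and passed with camera (Benjamini-Hochberg adjusted p = 0.0162; adjusted p = 0.642 with an estimated correlation). Without HS IMF 1 its camera adjusted p was 0.0628, and without both HS IMF 3 and HS SCF 4 it was 0.0537. With fry the Benjamini-Hochberg adjusted p was 0.0692. The mean of the list per sample had a median of 9.81 in IMF and 10.5 in SCF. That of the adipocyte identity list was lower in IMF as well, at 10.7 against 11.3. Whether fatty acid synthesis genes were lower beyond a dilution of fat cell transcripts by muscle RNA was not tested.

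Adipocyte identity genes had a median of −0.74 and did not pass as a list (camera, Benjamini-Hochberg adjusted p = 0.0684). Of 16, CFD, the adipokine adipsin (−1.90 ± 0.37 SE), and AQP7, a glycerol channel (−1.18 ± 0.33), were lower and none was higher; 3 were lower when adjusted over the list alone. In the triacylglycerol synthesis list (11 genes, median −0.59, adjusted p = 0.103 by the same test) the acyltransferase AGPAT3 was lower (−0.73 ± 0.20), and DGAT2, of the last step of the pathway, did not pass (−1.13 ± 0.34); adjusted over the list alone, 4 were lower and 1 higher. In the lipolysis list (8 genes, median −0.69, adjusted p = 0.172) the lipid droplet protein PLIN2 (−1.74 ± 0.49) and AQP7 were lower, and 3 were lower when adjusted over the list alone. Of 17 fatty acid oxidation genes, UCP3, the uncoupling protein of muscle (6.02 ± 0.29), and CPT1B, the muscle carnitine palmitoyltransferase (1.80 ± 0.29), were higher and 3 were lower, among them CPT2 (−1.01 ± 0.19) and UCP2 (−1.08 ± 0.26), with the same counts when adjusted over the list alone. AQP7 passed in 9 of 24 alternatives (limma, Benjamini-Hochberg adjusted p from 0.00147 to 0.118), PLIN2 in 13 of 24 (0.0152 to 0.106), AGPAT3 in 14 of 24 (0.0294 to 0.198) and UCP2 in 16 of 24 (0.00576 to 0.133). The oxidation list did not pass (adjusted p = 0.860), and its median, −0.41, and mean, 0.17, differed in sign.

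Several genes of other lists differed between the depots while their lists did not pass with camera and Benjamini-Hochberg adjustment. TNC, the matrix protein tenascin C, was higher in IMF by 4.75 ± 0.48 (SE), one of 3 higher and 2 lower of 20 fibrillar collagen and matrix genes (4 higher and 7 lower adjusted over the list alone; list adjusted p = 0.702). DLK1, an inhibitor of adipogenesis, was higher by 2.99 ± 0.48, while the stromal genes PDGFRA (−0.73 ± 0.21), CD34 (−0.67 ± 0.20) and DPP4 (−0.94 ± 0.27) were lower, of 15 progenitor and stromal genes (1 higher and 5 lower adjusted over the list alone; list adjusted p = 0.394). Of 15 insulin and glucose handling genes, PFKM, the muscle phosphofructokinase (4.43 ± 0.24), and LDHA (1.54 ± 0.21) were higher, and LDHB (−0.92 ± 0.23) and PC, pyruvate carboxylase (−1.37 ± 0.36), were lower (4 and 4 adjusted over the list alone; list adjusted p = 0.481, median −0.11 and mean 0.17). The 3 stromal genes were lost in most of the alternatives: PDGFRA passed in 9 of 24 (limma, Benjamini-Hochberg adjusted p from 0.0126 to 0.209), CD34 in 11 of 24 (0.0190 to 0.239) and DPP4 in 9 of 23 (0.0228 to 0.161), while LDHB passed in 16 of 24 (0.00495 to 0.0977) and PC in 15 of 24 (0.000798 to 0.128). A further probe set of PC, too dim to be tested with the others, lay in the opposite direction (1.38, adjusted p = 0.00841 with no filter), and further probe sets of TNC (−0.14), LDHA (−0.59) and PDGFRA (0.36 and 0.0018) differed in sign without passing.

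Of 15 secreted adipokine genes, INHBA, a subunit of activins (3.50 ± 0.96 SE), and NAMPT, of NAD synthesis (1.48 ± 0.35), were higher, and IL6 (−2.30 ± 0.29) and ANGPTL4, an inhibitor of lipoprotein lipase (−1.68 ± 0.31), were lower (2 and 3 adjusted over the list alone; list adjusted p = 0.860 by camera with Benjamini-Hochberg adjustment). Of 19 Wnt, TGF-beta and BMP genes, TGFB3 (2.22 ± 0.31) and DKK3, a secreted Dickkopf family protein (2.63 ± 0.28), were higher, and BMP2 (−1.21 ± 0.31) and FZD4, a Wnt receptor (−0.97 ± 0.29), were lower (3 and 2 adjusted over the list alone; list adjusted p = 0.242). Of 19 immediate early and stress genes, 5 were higher, among them the heat shock genes DNAJB1 (2.11 ± 0.26) and HSPA1A (1.45 ± 0.25) and ATF3 (1.48 ± 0.27), and 1 was lower (5 and 2 adjusted over the list alone). That list had a median of −0.10, a mean of 0.23 and an adjusted p = 0.172. MBP (−1.67 ± 0.20) and S100B (−1.60 ± 0.20) of the Schwann cell and nerve list were lower, the same 2 of 7 adjusted over the list alone. The list did not pass with camera (adjusted p = 0.394) and passed with fry (Benjamini-Hochberg adjusted p = 0.00560). Which cells carried these transcripts was not tested. INHBA passed in 11 of 23 alternatives (limma, Benjamini-Hochberg adjusted p from 0.000511 to 0.122), and its signal of 0.29 in HS IMF 3 lay within the SCF range of 0.01 to 18.7. FZD4 passed in 9 of 24 (0.0103 to 0.213) and BMP2 in 15 of 24 (0.0113 to 0.101). Further probe sets of NAMPT (−0.084), HSPA1A (−0.44 and −0.30), MBP (0.23 and 0.45) and AGPAT3 (0.18) differed in sign without passing.

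Of 4 further lists, 1 or 2 genes passed. The cell cycle genes BIRC5 (−1.25 ± 0.28 SE) and TYMS (−0.75 ± 0.20) were lower of 11 (4 lower adjusted over the list alone; list camera Benjamini-Hochberg adjusted p = 0.172), the homeobox gene IRX3 (−1.52 ± 0.40) of 13 (1 lower; 0.291), the mitochondrial COX7A1 of the thermogenic list was higher (1.73 ± 0.32) of 6 (1 higher; 0.335) and the sterol enzyme LSS lower (−1.25 ± 0.36) of 12 cholesterol genes (0 adjusted over the list alone; 0.832). LSS passed in 12 of 24 alternatives (limma, Benjamini-Hochberg adjusted p from 0.0124 to 0.135), IRX3 in 14 of 24 (0.00219 to 0.0895) and TYMS in 15 of 24 (0.0129 to 0.161). Another probe set of COX8B, a subunit of complex IV in the thermogenic list, was higher in IMF (adjusted p = 0.000866), while the brightest probe set of the gene, which the list counts use, did not pass (−0.41 ± 0.17). By the brightest probe set of each gene, no gene of the respiratory chain (list adjusted p = 0.832), endothelial cell (0.903), erythroid (0.399) or agouti and melanocortin (0.885) lists passed, over all genes or adjusted over the list alone. The endothelial median was −0.10 and its mean 0.05.

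**Figure D3:**
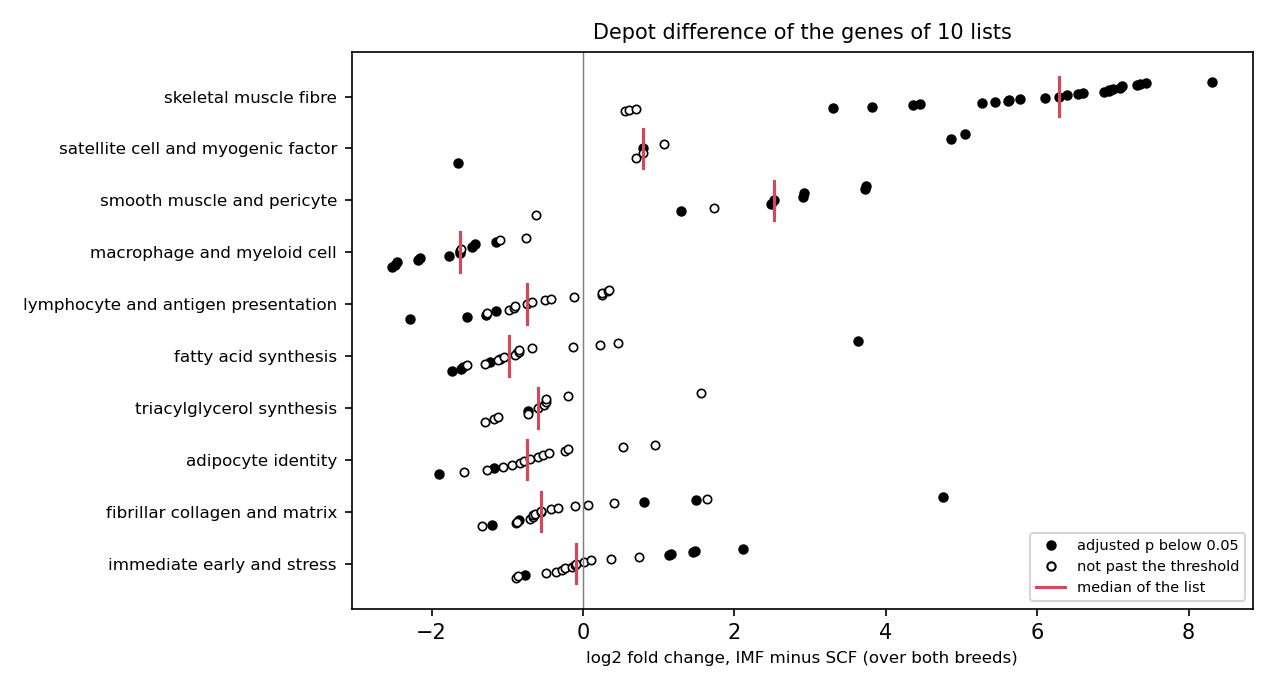
Log2 difference between IMF and SCF (x axis) of each measured gene in each of the gene lists (y axis); filled points had an adjusted p below 0.05 over all probe sets, open points did not, and the red line is the median of the list. The skeletal muscle fibre list lay highest, with a median of 6.29, and the macrophage and myeloid cell list lowest, with a median of −1.63.

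Within each breed, the depots differed at 516 probe sets in JB, 362 higher and 154 lower in IMF, and at 558 in HS, 303 higher and 255 lower, by limma with Benjamini-Hochberg adjustment. These counts rest on a spread shared over all groups. With only the compared groups in the fit, or with array weights, the JB count rose and the HS count fell, as given below. In HS, 237 were higher and 393 lower in the values as deposited, a share of 37.6% higher against 54.3% after quantile normalization. ASIP differed between the depots by −0.54 ± 0.40 (SE) in JB and 0.55 ± 0.40 in HS and passed in neither. Whether the depots differ more in one breed than in the other was tested through the interaction of breed and depot.

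No probe set passed for the interaction by limma with Benjamini-Hochberg adjustment, and 359 passed at an unadjusted p under 0.05, where 840.55 would be reached with no difference. The count was 0 in every other setting that kept all 12 samples, limma treat, array weights and the trended and robust variance model among them, 1 without HS IMF 2 and 1 without HS SCF 4. The interaction estimate of ASIP was −1.10 ± 0.56 (SE) (adjusted p = 0.990 by limma with Benjamini-Hochberg adjustment), so the depots were not shown to differ in it. The smallest p belonged to PDE4DIP (2.69 ± 0.41, adjusted p = 0.400), followed by MARCKSL1, a regulator of actin (−2.24 ± 0.40, adjusted p = 0.920). AMIGO2, an adhesion molecule (2.18), MME (2.31), NDUFS3, of complex I (1.86), TCAIM (1.44), RGS16, a regulator of G-protein signalling (−1.77), ZFP36 (−1.68), SLC16A3, a lactate transporter (−1.60), and ADAM19 (−1.24) each had an adjusted p of 0.990.

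For gene lists, the interaction passed with camera of limma for 6 of 26 lists, 2 with the breed difference higher in IMF and 4 with it lower, and for 0 with an estimated correlation (lowest Benjamini-Hochberg adjusted p = 0.628 with an estimated correlation) and 0 with fry. The immediate early and stress list had a median breed difference of −0.10 in IMF and 0.49 in SCF (camera, Benjamini-Hochberg adjusted p = 1.36e-06), and 4 of its 19 genes passed as lower when adjusted over the list alone. The fatty acid synthesis list had medians of 0.25 and −0.28 (adjusted p = 0.0122 by the same test; adjusted p = 0.751 with an estimated correlation). None of the genes of the 6 lists passed over all genes.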

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

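Of the tests in this part, those on ASIP's neighbours, the muscle marker covariate for ASIP, the macrophage mean against other lists and the removal of JB SCF 6 and HS SCF 5 were chosen only after the result was seen. The covariate was added after the data were seen, but what it should show for the interaction lists was written before that result. The estimated correlation was a setting fixed beforehand, and it was taken as a test of genes varying together only after its result was seen. Groups of 3 samples were not tested for outliers.

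For 6 gene lists the breed difference differed between the depots by camera on the interaction. The median interaction was 0.51 for fatty acid synthesis (median breed difference 0.25 in IMF, −0.28 in SCF), 0.55 for cholesterol synthesis and uptake (0.57, −0.09), −0.43 for macrophage and myeloid cell (0.02, 0.47), −0.37 for lymphocyte and antigen presentation (−0.22, −0.04), −0.89 for erythroid (−1.04, −0.03) and −0.66 for immediate early and stress (−0.10, 0.49). The camera Benjamini-Hochberg adjusted p was 0.0122 for the fatty acid, cholesterol and erythroid lists, 0.0484 for the macrophage and lymphocyte lists and 1.36e-06 for the immediate early list; adjusted p = 0.628 with an estimated correlation for the immediate early list and 0.751 for the other 5.

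Without 1 sample, the camera adjusted p and median of the fatty acid list were 0.251 and 0.026 (JB IMF 2), 0.0793 and 0.33 (JB SCF 6), 0.110 and 0.46 (HS IMF 1), and 0.0996 and 0.30 (HS SCF 6). Those of the cholesterol list were 0.104 and 0.42 (JB IMF 2), 0.0962 and 0.55 (HS IMF 2), 0.0885 and 0.19 (HS IMF 3), and 0.0926 and 0.35 (HS SCF 6). Those of the erythroid list were 0.0602 and −0.82 (JB SCF 6), 0.186 and −0.20 (HS IMF 3), and 0.0886 and −0.67 (HS SCF 6). The macrophage list was lost without JB IMF 1 (0.0985), JB IMF 3 (0.507), JB SCF 5 (0.214), JB SCF 6 (0.245), HS IMF 1 (0.0540), HS IMF 2 (0.150), HS IMF 3 (0.184), HS SCF 4 (0.112) and HS SCF 5 (0.0863), its median then lying between −0.11 (JB IMF 3) and −0.57 (HS IMF 1). The lymphocyte list was lost without JB IMF 1 (0.154), JB SCF 5 (0.353), JB SCF 6 (0.275), HS IMF 1 (0.231), HS IMF 3 (0.0862), HS SCF 5 (0.251) and HS SCF 6 (0.121), its median then lying between −0.14 (HS IMF 1) and −0.43 (JB IMF 1).

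For these 6 lists, genes of a list varying together between samples is a possible explanation, as 0 of 6 passed with an estimated correlation. With the muscle marker covariate 6 of 6 passed by camera, at medians of 0.56 (fatty acid synthesis), 0.57 (cholesterol), −0.44 (macrophage), −0.39 (lymphocyte), −0.90 (erythroid) and −0.65 (immediate early). The macrophage and lymphocyte lists passed narrowly (camera adjusted p = 0.0482). The muscle fibre mean was close between the breeds, 12.3 in JB IMF and 12.2 in HS IMF, and 6.70 in JB SCF and 6.71 in HS SCF. The covariate could therefore hardly move these values, and it does not decide on muscle RNA. Without JB SCF 6 and HS SCF 5, the SCF samples with the highest muscle fibre means, 5 of the 6 calls ended with 2 samples left per SCF group: the adjusted p and median were 0.109 and 0.38 for fatty acid synthesis, 0.0622 and 0.46 for cholesterol, 0.501 and −0.24 for macrophage, 0.727 and −0.070 for lymphocyte and 0.0979 and −0.79 for erythroid, and whether the smaller number or the muscle content ended them was not tested. For the immediate early list the highest adjusted p of both settings was 1.46e-06. Only for the immediate early list did leaving out 1 sample never end the camera call (highest adjusted p = 0.00580, medians from −0.86 to −0.42). This argues against a single sample as the cause of that call. All these fits used the preset correlation, so they do not show that the difference itself holds. The breed difference of this list in SCF was lost without HS SCF 6 (camera adjusted p = 0.186).

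ASIP was higher in JB in both depots, though with a pseudocount of 1 it passed in neither (adjusted p = 0.474 in IMF and 0.239 in SCF). With the muscle marker covariate its highest adjusted p over both depots was 0.0177 (limma, Benjamini-Hochberg). The muscle fibre mean hardly differed between the breeds within a depot, so the covariate could hardly move the difference and decides nothing. The ASIP signal in JB was 355 to 678 in IMF and 493 to 788 in SCF, where the muscle fibre mean was far lower. This argues against muscle RNA as the source. Without JB SCF 6 and HS SCF 5 the difference in SCF was 3.96, against 4.49 with all samples, and the call ended (adjusted p = 0.0584) with 2 samples left per SCF group. Among the 10 nearest tested genes, which include AHCY, ITCH and RALY, the largest breed difference was 0.71 and 0 passed, with medians of 0.25 in IMF and −0.03 in SCF, which argues against a change shared with the neighbourhood. A base difference between the breeds under the probes could give the same picture; ASIP is read by 1 probe set, so this stays open.

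The macrophage and myeloid cell list was lower in IMF, where muscle RNA might dilute every fat cell transcript. The mean of the list minus the mean of the adipocyte and endothelial lists differed by −1.43 between IMF and SCF (exact p = 0.00216 over 924 relabelings), which argues against dilution alone, although muscle brings its own endothelium. The adipocyte mean differed by −0.67 (exact p = 0.0130) and the endothelial mean by 0.05 (exact p = 0.729). In the values as deposited the camera adjusted p of the list was 2.06e-08, which argues against the added quantile normalization as the source. The normalization behind the deposited values is not known, so the test does not reach it. With an estimated correlation the camera adjusted p of the list was 0.353. The 27 measured skeletal muscle fibre genes, at a mean of 11.5 to 12.7 in IMF and 5.88 to 8.01 in SCF, and the 14 macrophage genes share 0 genes with other lists.

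The samples were regrouped to see what a split without the real labels gives. Between the depots and for the interaction, 100 of the 200 possible splits were fitted. Between the depots, 1 of 100 fitted splits, the real one, reached 1848 probe sets, and the highest other had 116. No other fitted split came near that count. The other splits hold the large muscle difference within their groups, which can lower their counts, so they do not by themselves exclude chance. For list counts between the depots, 53 of 100 splits reached the real 5 and the highest other had 13, and for the interaction 48 of 100 reached the real 6 and the highest other had 14, so chance cannot be excluded for the number of lists. For interaction probe sets the real count was 0, which 100 of 100 splits reach whatever the data (highest other 5), so the splits say nothing about it. The breed comparisons and the depot comparisons within a breed have 10 splits each, too few for a share under 0.05. In IMF, 2 of 10 reached the real 4 probe sets (highest other 4, with JB IMF 2, HS IMF 2 and HS IMF 3 together) and 8 of 10 the real 2 lists (highest other 11; why a split gave more lists was not tested). In SCF, 1 of 10 reached the real 1 probe set (highest other 0) and 7 of 10 the real 5 lists (highest other 9). Within JB 1 of 10 reached the real 516 (highest other 0), and within HS 1 of 10 the real 558 (highest other 167).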

How the results depend on the processing

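Quantile normalization, which the design held ready as another setting, became the setting of the report by the rule of the design. The values as deposited, the removal of HS IMF 3 with HS SCF 4 and of JB SCF 6 with HS SCF 5, and the muscle marker covariate were chosen after seeing the data. The cause of a moved value was not tested.

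Counts of probe sets past the threshold moved as follows, by limma with Benjamini-Hochberg adjustment. Breed in IMF, 4 in the report, gave 2 with a pseudocount of 1, 0 with array weights, 0 with only the compared groups in the fit, 2 with 1 probe set per gene, 2 without JB SCF 6 and HS SCF 5 and 2 with the muscle marker covariate. Breed in SCF, 1 in the report, gave 0 with a pseudocount of 1, 12 with array weights, 0 with only the compared groups, 2 without HS IMF 3 and HS SCF 4 and 0 without JB SCF 6 and HS SCF 5. Depot over both breeds, 1848 in the report, gave 3154 with array weights, 1192 with 1 probe set per gene, 834 with treat against 1.2-fold and 799 without JB SCF 6 and HS SCF 5. The interaction, 0 in the report, gave 1 without HS IMF 3 and HS SCF 4, SELE; all groups are already in its fit, so only the compared groups gives no separate value. Depot in JB, 516 in the report, gave 4340 with array weights, 1038 with only the compared groups, 322 with 1 probe set per gene, 834 without HS IMF 3 and HS SCF 4 and 220 without JB SCF 6 and HS SCF 5. Depot in HS, 558 in the report, gave 184 with array weights, 158 with only the compared groups, 306 with treat against 1.2-fold, 365 without HS IMF 3 and HS SCF 4 and 224 without JB SCF 6 and HS SCF 5.

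Counts of gene lists moved too. Breed in IMF, 2 lists, gave 4 as deposited, 6 without HS IMF 3 and HS SCF 4, 0 with an estimated correlation and 0 with fry. Breed in SCF, 5 lists, gave 8 without HS IMF 3 and HS SCF 4, 1 without JB SCF 6 and HS SCF 5, 0 with an estimated correlation and 1 with fry. The 1 list with fry was agouti and melanocortin, and none of the 5 lists called by camera passed with fry. Depot, 5 lists, gave 8 with no filter and 2 with an estimated correlation. The interaction, 6 lists, gave 1 without JB SCF 6 and HS SCF 5, 0 with an estimated correlation and 0 with fry.

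With 1 sample left out, the counts ran from 0 to 7 probe sets and 2 to 7 lists for breed in IMF, 1 to 2 and 1 to 7 for breed in SCF, 942 to 2346 and 4 to 7 for depot, 0 to 1 and 2 to 10 for the interaction, 227 to 715 probe sets for depot in JB and 192 to 1114 for depot in HS. The median of the respiratory chain list in SCF ran from −0.39 to 0.11 and was positive without HS SCF 6 (0.11) and without JB SCF 6 (0.0061).

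Directions turned for other probe sets of named genes, listed here for the genes named in the report. PDE4DIP in IMF was −0.84 for the other probe set and −0.84 with 1 probe set per gene. Between the depots, other probe sets gave −0.14 for TNC, −0.21 for MYH1, 1.38 for PC (a dim probe set, adjusted p = 0.00841 with no filter), 0.23 and 0.45 for MBP, 0.18 for AGPAT3, −0.084 for NAMPT, −0.59 for LDHA, −0.44 and −0.30 for HSPA1A and 0.36 and 0.0018 for PDGFRA, and COX8B, not past on its brightest probe set, was higher on another. Among genes not past the threshold, other probe sets gave 0.28, 0.71, 0.33 and 0.24 for THBS1 and 0.36 for SESN2 in IMF, −0.17 for GRO1, −0.11 for IER2 and −0.54 for POMC in SCF, and 0.053 for SLC16A3 and −0.46 for PDE4DIP in the interaction. Of the 79 named depot genes past the threshold, 50 passed in every alternative and 29 were lost in at least 1. The setting with 1 probe set per gene is part of that count and can read a gene through another probe set. MYL11 and MYH7 were lost only there. Other probe sets taken singly are not part of that count.

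A block for the replicate numbers, which are nested in depot and so cannot block the depot comparison, gave 2 probe sets for breed in IMF, 1 for breed in SCF and 0 for the interaction. With the block, ASIP in IMF (adjusted p = 0.0525), LTBP2 in IMF (0.350) and the respiratory chain list in SCF (0.0570) were lost. The numbers do not pair the breeds: of 6 same-numbered pairs 1 had a residual correlation over 0.1, the range was −0.28 to 0.12, and 3 samples best matched their own number.

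The deposited signals hold no detection calls, so dim genes near the background, such as ASIP in HS at 0.06 to 33.9 in SCF, have a fold change that depends on the pseudocount. With a pseudocount of 1 the log2 difference was 6.25 for ASIP in SCF, 4.00 for ASIP in IMF and 11.79 for MYH1 between the depots.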

Other observations

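Everything in this part, the tests of sample origin included, was chosen after the values were seen, except the gene list tests. Their lists, threshold and settings were fixed before the data were examined.

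Some genes stood out in single samples or pairs. HS IMF 3 and HS SCF 6 stood apart from the other 10 samples on 9 probe sets, all of BOLA-DQ genes, the polymorphic chains of MHC class II, 2 higher and 7 lower. A BOLA-DQB1 probe set had deposited signals of 41414 and 222742 in these samples and 33.9 to 148 elsewhere. HS IMF 2 and HS SCF 4 shared 14 such probe sets, 13 higher and 1 lower, 7 of them unnamed. The named ones were the lipid enzymes MBOAT1 and LCAT, the retinol dehydrogenase RDH10, and ZBTB44, EMX2, HMGXB4 and ZNF398. SELE, the adhesion molecule E-selectin, had signals of 4492, 7051 and 8802 in the 3 JB SCF samples, 1697 in HS SCF 4 and at most 147 elsewhere. MC4R, a melanocortin receptor, had a signal of 1515 in HS SCF 4 only.

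BOLA-DQ signals shared by samples of different depots are a reason to ask whether some pairs come from 1 animal. If IMF sample n and SCF sample n + 3 of a breed did, they could share more outlying probe sets than other matchings. Of 44 probe sets with a gap of 1.5 log2 units, 12 lay on such pairs, against a mean of 10 per matching (exact p = 0.389 over 36 matchings). The residual correlation of these pairs averaged 0.0909 and the highest matching 0.290 (exact p = 0.222). The question stays open; genotypes of the samples, or the animal numbers, would settle it.

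A breed difference of ASIP in both depots could come from the regulation of the gene or from bases under its probes, of which 1 probe set alone was available. Reads or a PCR placed outside the probe region, in JB and HS fat, would separate these; if the signal of the HS samples stayed near the background there too, the probe explanation would fall. The higher smooth muscle and pericyte list in JB IMF, with a mean of 11.6, 11.2 and 12.1 in JB and 11.3, 10.4 and 10.2 in HS, had an adjusted p = 0.693 with an estimated correlation. The endothelial list, with a median of −0.27, did not pass (camera, Benjamini-Hochberg adjusted p = 0.0924; adjusted p = 0.822 with an estimated correlation), so nothing is concluded on vessels.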
